A study of Mus musculus with 15 samples.

How the data were processed

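RNA of 15 mouse samples, 12 medulloblastomas and 3 normal cerebella, had been hybridised to 15 one-colour (Cy3) Agilent mouse arrays, with 1 array per sample and no pooling. Samples were grouped by the tissue, type and dose in the labels into 5 groups of 3 arrays: normal cerebellum, S-type at 0 Gy, S-type at 0.2 Gy, R-type at 0.2 Gy and R-type at 1.5 Gy. Each array file held spot intensities on a linear scale, which the authors had made, per the file headers, by scanning and extraction with background subtraction and spatial detrending and without scaling between arrays; the extraction tool was Agilent Feature Extraction 9.5.1 per the submitters' processing notes. The files also held raw median pixel intensities of each spot and its local background, but no mean pixel intensities. The deposited series table held log2 values in 15 columns, and how the authors made it was not stated. Its differences between arrays correlated at 0.99986 to 0.99999 with those of the log2 processed signals scaled at the 75th percentile, and the columns of MB1 and MB2 summed to 0 at every probe, so that the table was read as log2 values less the mean of these 2 arrays. Why these arrays served as reference, and the scale before that step, stay unknown. The column medians of that table were 0.00239, 0.0819 and 0.089 for the normal cerebella and 0.0506, −0.0506, 0.106, 0.0682, −0.0795, 0.0524, 0.0702, 0.13, 0.127, 0.0908, 0.151 and 0.0989 for MB1 to MB12. All 15 columns were used, as an alternative input only.

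The processed signal was put on the log2 scale and the 75th percentile of each array was subtracted. Spots of the same probe were averaged, control spots were left out, and 76 probes whose spots were marked as non-uniform or as population outliers on some array were left out. The files gave no gene symbols. Of 41174 probes, 26382 carried a RefSeq accession and 24836 were named through it from a table of RefSeq genes, giving 17174 gene symbols; the other 16338 probes kept their own name. The gene table and the array annotation rest on different genome assemblies, so that chromosomes and gene order are given and coordinates are not. For each of the 32678 names the probe with the highest mean over the 15 arrays was used, and the 21671 with a signal well above background on at least 3 arrays were tested, 13432 of them with a symbol. Among 5397 genes with several tested probes, probes gave opposite calls for 385 between tumours and normal cerebella, 60 between the types and 1 between the types at 0.2 Gy, none of them a gene named in the text. Where no probe of a gene was well above background on any array of a group, its change was given only as a bound, with the signal of each array of that group raised to at least the lowest signal well above background on that array.

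Group means were fitted with limma 3.58.1 in R 4.3.3, with 1 pooled spread per gene over the 5 groups (10 residual degrees of freedom, 1.71 prior), eBayes moderation and two-sided tests, and the contrasts were adjusted by Benjamini-Hochberg at 0.05 over all tested genes. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6. The comparisons were tumours against normal cerebella (mean of the 4 tumour groups), R-type against S-type tumours, the types at 0.2 Gy, the doses within each type, and each tumour group against normal cerebellum. Before the data were examined, the groups, comparisons, gene lists, alternatives and the rule for naming genes were fixed. The rule took Ptch1, the 8 highest and 8 lowest changes between tumours and normal cerebella and the 6 highest and 6 lowest of each other comparison, among genes that passed, whose values did not overlap and that were well above background on every array of the higher group. It also took up to 4 members with the smallest adjusted p of each list described, and Plagl1, Cdkn1c, Tgfb2 and Igf2 between the types. Names that are only clone or accession names were skipped.

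Of 27 gene lists with 363 genes, 349 of the genes were on the array and 335 were tested; the list of sex-linked genes served only to check labels, and 26 were tested with camera of limma at a preset correlation of 0.01, adjusted over the lists. The correlation estimated from the data was the alternative. The lists held SHH pathway and targets, granule neuron precursors, DNA replication, mitosis, p53 targets, mature granule neurons, Purkinje cells, GABAergic interneurons, astrocytes and Bergmann glia, oligodendrocytes and their precursors, microglia and macrophages, lymphocytes, endothelium, meningeal fibroblasts, choroid plexus, blood, imprinted genes, TGF-beta, WNT, Notch, interferon and MHC class I, immediate early genes, hypoxia and glycolysis, ribosomal proteins and DNA repair. Genes of chromosome 13 were tested as 4 sets in the same way, with two-sided exact permutation tests of the median of each tumour. Lower stretches along chromosome 13 were found, relative to the S-type tumours, as the run of ordered genes for which 1 lower level inside and 0 outside left the smallest sum of absolute deviations, and were set against 1000 shuffled gene orders. An S-type tumour was measured against the mean of the other S-type tumours.

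Depth was read as signal over background: the median spot was 3.89 to 5.3 times its local background, and negative control spots (153 per array) had a median of 56.0 to 63.0. No spot was saturated. The arrays lay on 4 slides, with at most 1 array of a group on a slide, and slide 4 held no normal cerebellum; slide was therefore used as a term in an alternative fit and differences within slides were taken.

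Simulated data had the arrays and the pooled gene spreads of the real data, with independent noise. In each comparison 67, 67 and 66 genes carried a change of 0.5, 1 and 2 log2 units. The workflow was tested on the recovery of these genes. It recovered 37.3%, 76.1% and 86.4% of these between tumours and normal cerebella, 43.3%, 85.1% and 92.4% between the types, 20.9%, 68.7% and 86.4% between the types at 0.2 Gy, 26.9%, 56.7% and 86.4% between doses in S-type and 28.4%, 53.7% and 78.8% between doses in R-type tumours. Unchanged genes called were 14, 8, 5, 7 and 6 in the same order. In simulated profiles of 410 genes with a stretch at −0.75, 99% of the ends were found within 5 genes.

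Alternatives tried were normexp background correction (offset 50, on median pixel intensities since mean ones were not in the files), quantile normalization, scaling by array median, the series table, other filters on dim probes, the mean of all probes of a gene, fits of only the compared groups, sex, age and slide as terms, array weights, a robust fit with a mean-variance trend, other thresholds and set sizes, and leaving out each array in turn. The fit with age held the tumours only. Leaving out MB2, MB3 and MB6 together, and leaving out chromosome 13, were added after seeing the data, as were other scalings and filters for chromosome 6. Copy number arrays were not analysed here. Results of some genes that the naming rule takes are not reported here.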

Results

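Gene expression was measured in 15 samples of mouse cerebellar tissue, with 1 one-colour Agilent array for each sample. Of these, 12 were medulloblastomas, tumours of the cerebellum, from mice heterozygous for Ptch1, the receptor that restrains the sonic hedgehog (SHH) pathway, and 3 were normal cerebella. The labels name the tumours MB1 to MB12 and sort them into S-type and R-type, without saying what the letters stand for. S-type tumours came from mice that had received 0 Gy (MB1 to MB3, n = 3) or 0.2 Gy of X-rays (MB4 to MB6, n = 3), and R-type tumours from mice that had received 0.2 Gy (MB7 to MB9, n = 3) or 1.5 Gy (MB10 to MB12, n = 3). Irradiation took place on postnatal day 1, and the mice were followed until they were moribund. Age at sampling, for which the labels give no unit, was 87 to 127 for R-type tumours, 128 to 173 for S-type tumours and 103 to 113 for the normal cerebella, so that age separated the tumour types completely. The genotype and strain of the mice with normal cerebella are not given. The copy number arrays that the series title mentions were not analysed here.

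Between 24329 probes (MB3) and 27358 probes (MB5) of 41174 were well above background on an array, or 59.1 to 66.4%. The 75th percentile of the signal was 1181.6 to 1369.3 on R-type arrays, 1240.6 to 1614.0 on S-type arrays and 1520.3 to 1566.8 on arrays of normal cerebellum. The number of arrays per group limits the precision of every comparison, and the p-values measure the spread between these mice. Correlations across genes, which are not independent replicates, were 0.9902 to 0.992 between normal cerebella, 0.957 to 0.9908 between tumours and 0.7732 to 0.8334 between a tumour and a normal cerebellum. In a principal component analysis the first component held 78.3% of the variance and parted normal cerebella from tumours, and the second held 5.47% and placed the S-type tumours at 20.06 to 53.97 and the R-type tumours at −45.96 to −22.52. The Y-linked genes Ddx3y, Eif2s3y and Kdm5d were well above background on the MB6 array only, the 1 tumour labelled male. Xist, expressed from the inactive X chromosome, was well above background on the other 14 arrays, though MB3 (−4.21) and MB9 (−4.04) lay below the remaining female tumours, which spanned −1.44 to 1.26. Values are log2 signals relative to the 75th percentile of the array.

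Ptch1, the targeted gene, was measured on chromosome 13 by a probe whose place relative to the targeted part of the gene is not known, so whether transcripts of the targeted allele add to its signal is not known. Its log2 signal was −3.03, −3.20 and −3.33 in the normal cerebella. In the S-type tumours at 0 Gy it was −1.54 (MB1), −1.99 (MB2) and −1.47 (MB3), and at 0.2 Gy −1.60 (MB4), −1.77 (MB5) and −2.08 (MB6). In the R-type tumours at 0.2 Gy it was −3.16 (MB7), −2.98 (MB8) and −3.16 (MB9), and at 1.5 Gy −3.16 (MB10), −2.70 (MB11) and −3.06 (MB12). The S-type tumours thus lay above every normal cerebellum and every R-type tumour, and the R-type tumours overlapped the normal cerebella.

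The comparison of the 12 tumours with the 3 normal cerebella asked how tumour tissue differed from the organ in which it arose. Most listed genes of cell division and of granule neuron precursors were higher in the tumours, and most of mature granule neurons, Purkinje cells, interneurons, astrocytes and oligodendrocytes were lower. Of these lists only that of Purkinje cells kept its call with an estimated correlation between genes. Mki67, a marker of dividing cells, was higher by 9.95 on the log2 scale (SE 0.287), at 5.79 ± 0.17 (SD, n = 12) against −4.16 ± 1.01 (SD, n = 3), with an adjusted p of 2.04e-11 in limma. Atoh1, the transcription factor of granule neuron precursors, was at least 213-fold higher. Calb1, the calcium-binding protein of Purkinje cells, was lower (log2 change −9.37, SE 0.963, adjusted p 1.73e-06), at −3.27 ± 1.84 (SD, n = 12) against 6.10 ± 0.03 (SD, n = 3), with signal well above background in 10 of the 12 tumours. Of 21671 tested genes, 13432 of them with a symbol, 17094 changed, 9417 being higher and 7677 lower in the tumours, and 5292 of the higher and 4619 of the lower ones changed at least 2-fold. The median over all genes was 0.135 with the scaling used and −0.0392 without scaling, and the changes are read relative to it.

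Among the other genes with the largest rises, Igfbpl1 was at least 531-fold, Tk1 at least 404-fold, Nhlh1 at least 328-fold, Insm1 at least 302-fold and Dtl at least 215-fold higher in the tumours. Ska1, a mitotic spindle gene, was higher too, but its tested probe was not well above background in normal cerebellum while another of its probes was, so no fold is given. Besides Calb1, the genes named for their falls were Gng13 (−9.03, well above background in 11 of 12 tumours), Crtam (−8.66, in 9), the neurofilament gene Nefl (−8.80, in 7), Ppp1r17 (in 6), Etnppl and Cck (in 3 each) and the neurofilament gene Nefh (in 2). Tumours without signal above background enter these values at background level, so that the sizes and their order depend on it, and none is given where at most 6 tumours were above it. Ptch1 rose by 0.80 (SE 0.134, adjusted p 0.000135), from −3.19 ± 0.15 (SD, n = 3) to −2.39 ± 0.71 (SD, n = 12), with overlapping values.

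Of 26 gene lists, 12 differed between tumours and normal cerebellum by camera with a preset correlation of 0.01. All 18 tested genes of the mitosis list rose (Aurkb at least 109-fold, Kif11 at least 65.6-fold, Tpx2 by 6.58), with an adjusted p of 1.25e-09 and an adjusted p = 0.293 with an estimated correlation. All 18 genes of DNA replication rose (Mcm6 by 5.90, Tyms by 5.66, E2f1 by 5.44; adjusted p 2.45e-08, adjusted p = 0.347 with an estimated correlation). So did 14 of 15 DNA repair genes (Brca1 by 5.49; adjusted p 8.34e-06, adjusted p = 0.293 with an estimated correlation). All 16 ribosomal protein genes rose (Rps9 by 1.99; adjusted p 2.29e-06, adjusted p = 0.384 with an estimated correlation). Of 18 genes of granule neuron precursors 12 rose, among them Sox11 by 6.94 and Dcx by 6.73, and 2 fell (adjusted p 0.00389, adjusted p = 0.293 with an estimated correlation). Of 17 SHH pathway genes and targets 13 rose, among them Ccnd2 by 7.61, Sfrp1 by 6.98, Mycn by 6.30 and Gli2 by 4.70, and 3 fell (adjusted p 0.00389, adjusted p = 0.351 with an estimated correlation). Of 12 genes of microglia and macrophages 11 rose, among them Aif1 by 3.70 and C1qc by 3.12 (adjusted p 0.00107, adjusted p = 0.413 with an estimated correlation).

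The markers of mature cells went the other way. All 12 Purkinje cell genes fell (Pcp2 −6.19, Slc1a6 −6.13, Rora −4.71; adjusted p 1.26e-06), and this list alone also passed with an estimated correlation (adjusted p 0.0246). All 15 genes of mature granule neurons fell (Chn2 −6.82, Snap25 −5.73, Cbln1 −2.31; adjusted p 1.34e-05, adjusted p = 0.351 with an estimated correlation). Of 12 oligodendrocyte genes 11 fell, with Mal at −4.18 and Mog at least 17.9-fold lower (adjusted p 0.000334, adjusted p = 0.293 with an estimated correlation). Of 8 genes of GABAergic interneurons 7 fell, with Gad1 at −8.02, and 1 rose (adjusted p 0.00389, adjusted p = 0.293 with an estimated correlation). Of 13 genes of astrocytes and Bergmann glia 10 fell, with Aldoc at −6.29 and Gja1 at −4.24 (adjusted p 0.0054, adjusted p = 0.413 with an estimated correlation).

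The other 14 lists did not pass as lists. In the Notch list 8 genes of 11 rose, with Hey1 at 2.27 (adjusted p 0.0545). In the p53 list 12 of 19 rose and 5 fell, with Pmaip1 at 11.3-fold and Bax at a log2 change of 1.63 (adjusted p 0.198). In the TGF-beta list 12 of 17 rose and 4 fell, with Smad2 at 1.40 and Smad7 at −2.55 (adjusted p 0.227). Of the list of oligodendrocyte precursors, 3 of 6 genes rose, with Pdgfra at 4.30 (adjusted p 0.239). Imprinted genes rose in 5 and fell in 8 of 18 cases, with Nnat at 4.08 and Snrpn at −2.59 (adjusted p 0.241). Immediate early genes rose in 4 and fell in 7 of 12, with Egr2 at least 82.2-fold higher and Fos at −3.36 (adjusted p 0.278). Hypoxia and glycolysis genes rose in 4 and fell in 7 of 13, with Hk2 at 3.05 and Slc2a1 at −0.95 (adjusted p 0.282). Interferon and MHC class I genes rose in 7 and fell in 2 of 14 (adjusted p 0.356). Choroid plexus genes fell in 2 of 7 and endothelial genes rose in 6 and fell in 2 of 12 (adjusted p 0.567 for both). Blood genes rose in 2 and fell in 3 of 5 (adjusted p 0.61). Lymphocyte genes rose in 1 and fell in 2 of 5 (adjusted p 0.753). WNT targets rose in 4 and fell in 3 of 12, with a median of −0.22 and a mean of 0.13. Meningeal genes rose in 4 and fell in 3 of 9, with a median of 0.52 and a mean of −0.23 (adjusted p 0.995 for both the WNT and the meningeal list, with the test pointing down). Counts adjusted over the list alone were the same for all 26 lists.

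**Figure D1:**
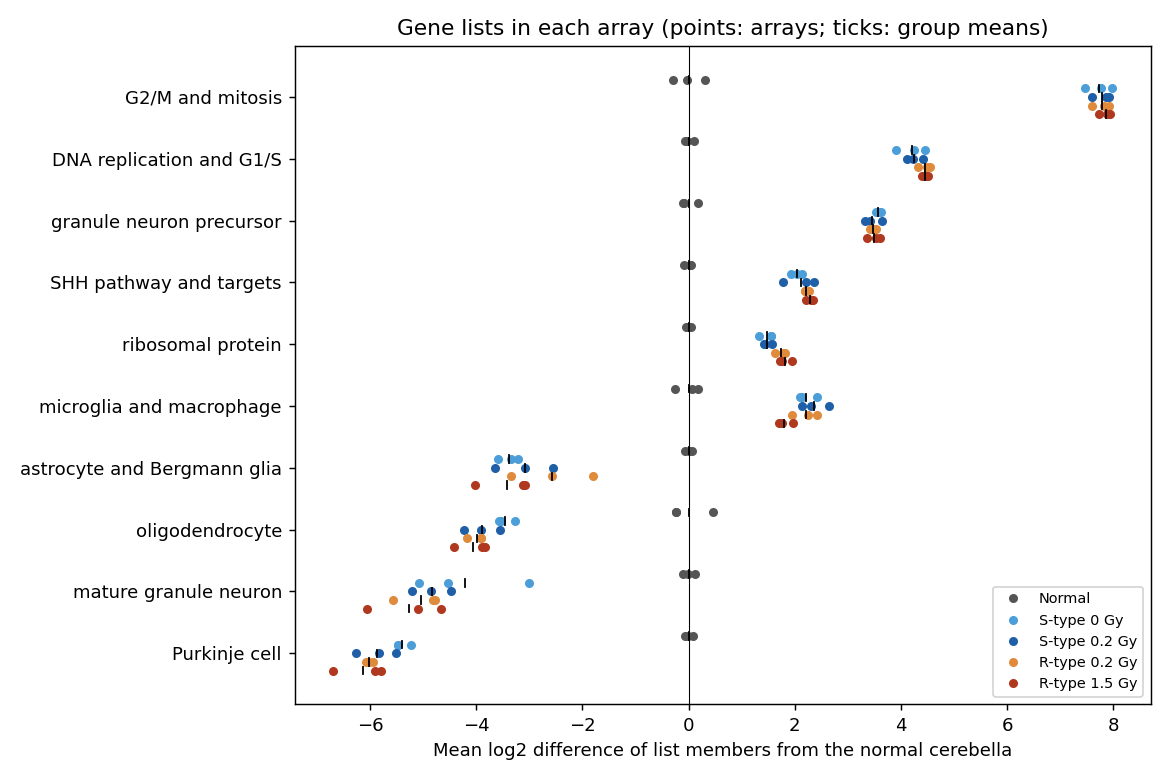
Mean log2 difference of the members of 10 gene lists from the normal cerebella, with 1 point per array and a tick at each group mean. The mitosis and replication lists lie above the normal cerebella in all 12 tumours, and the Purkinje cell and mature granule neuron lists below them.

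Each tumour group differed from normal cerebellum in a like number of genes: 16088 for S-type at 0 Gy, 16008 for S-type at 0.2 Gy, 16054 for R-type at 0.2 Gy and 16153 for R-type at 1.5 Gy. Slide 4 of 4 held no normal cerebellum. On the other slides the mean difference of the mitosis list was 7.44 to 7.97 and that of the Purkinje cell list −5.99 to −5.74, and with slide as a term the number of genes changed, tumour versus normal, was 16901.

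R-type and S-type tumours (6 each) were compared to ask how the types differed. The labels give no S-type tumour at 1.5 Gy and no R-type tumour at 0 Gy, so type, dose and age varied together. Ptch1 was lower in R-type tumours by 1.30 log2 units (log2 change −1.30, SE 0.12, adjusted p 5.43e-05), at −3.04 ± 0.18 (SD, n = 6) against −1.74 ± 0.25 (SD, n = 6), and by −1.51 to −1.13 within the 4 slides. Plagl1, an imprinted gene of a zinc finger transcription factor, was higher by 2.72 (SE 0.218, adjusted p 2.33e-05), at 1.75 ± 0.50 (SD, n = 6) against −0.97 ± 0.34 (SD, n = 6), and by 2.26 to 3.28 within slides. Tgfb2, a TGF-beta ligand, fell by 1.33 (SE 0.13, adjusted p 7.7e-05), to −0.23 ± 0.30 (SD, n = 6) from 1.10 ± 0.36 (SD, n = 6). Within slides it changed by −1.89 to −0.97. Cdkn2a, which encodes inhibitors of cyclin-dependent kinases and of Mdm2, fell by 2.80 (SE 0.297, adjusted p 0.000135), to −2.30 ± 0.70 (SD, n = 6) from 0.50 ± 0.79 (SD, n = 6).

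In all, 4573 genes changed between the types, 2398 higher and 2175 lower in R-type tumours, and 261 of the higher and 397 of the lower ones changed at least 2-fold. Among the largest rises were those of Mgarp (3.68, SE 0.302, adjusted p 2.64e-05), Plagl1, Trim55 (2.55, adjusted p 0.0115) and the growth factor gene Mdk (2.54, adjusted p 0.00766). The genes named for their falls were Mab21l2 (adjusted p 0.00844), the prolactin gene Prl (−4.30, adjusted p 0.0039), Frmd5 (−2.86, adjusted p 0.00322), Cdkn2a, Dmrta1 (at least 2.23-fold lower, adjusted p 0.00616) and Bend7 (adjusted p 0.000419). Of the 6 R-type tumours, Frmd5 was well above background in 5, Prl in 4, Mab21l2 in 3 and Bend7 in 1, and no size is given for the last 2. Igf2 was higher by 1.65 (SE 0.439, adjusted p 0.0214), with overlapping values and differences of 0.29 to 3.36 within slides, and without MB9 its adjusted p was 0.0523. Cdkn1c stood at 0.51 with an adjusted p of 0.19.

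**Figure D2:**
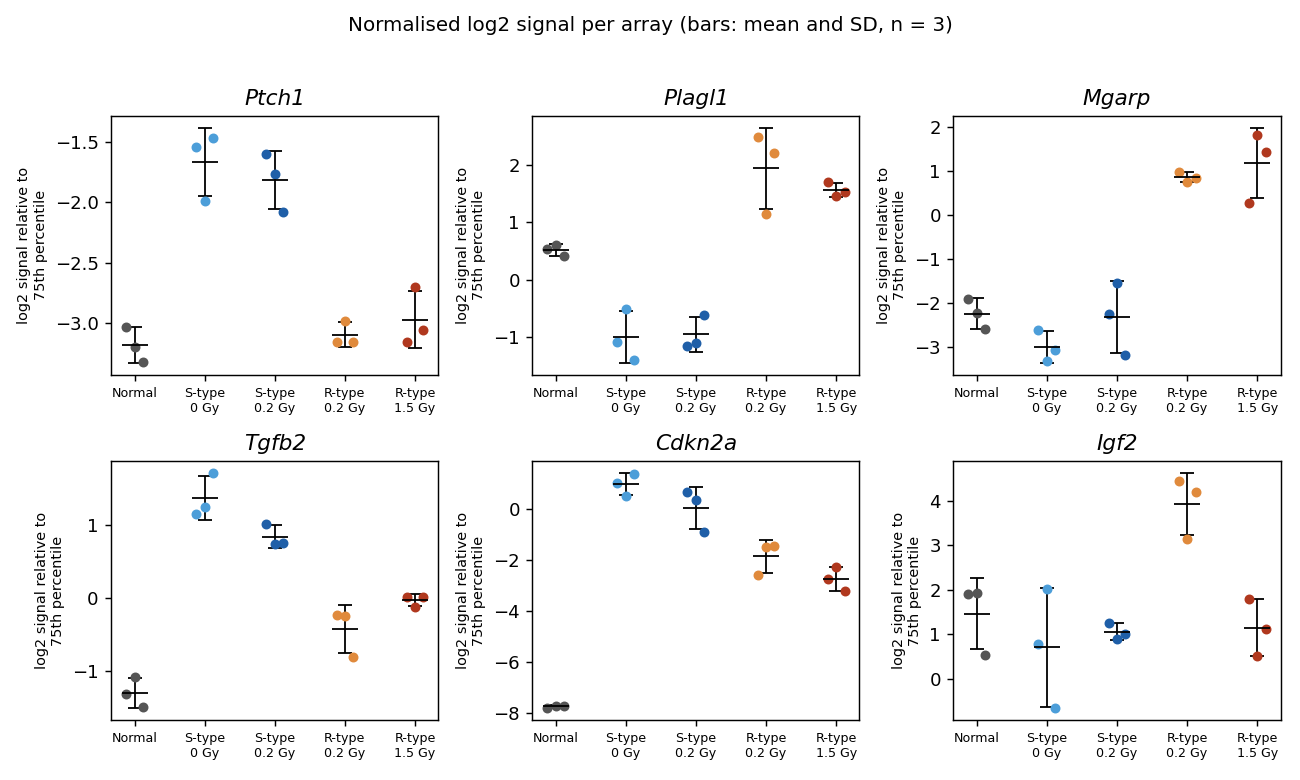
Normalised log2 signal of Ptch1, Plagl1, Mgarp, Tgfb2, Cdkn2a and Igf2 on each array by group, with the group mean and SD (n = 3). Ptch1 lies between −2.08 and −1.47 in S-type tumours and between −3.16 and −2.70 in R-type tumours.

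Of the 26 lists, 4 differed between the types, none of them with an estimated correlation. All 16 ribosomal protein genes were higher in R-type tumours (Rps15 by 0.48, Rpl5 by 0.35, Rps2 by 0.33; median 0.30, adjusted p 6.38e-08, adjusted p = 0.932 with an estimated correlation), with mean differences of 0.112 to 0.39 within slides. Of 13 genes of hypoxia and glycolysis 4 rose, the carbonic anhydrase gene Car9 by 0.80, the glucose transporter gene Slc2a1 by 0.60, Ldha by 0.59 and Aldoa by 0.54, and 10 rose when adjusted over the list alone (median 0.60, adjusted p 0.00085, adjusted p = 0.932 with an estimated correlation). Its mean difference ranged from 0.0133 to 1.02 within slides. Of 18 DNA replication genes 5 rose, among them Rrm2 by 0.60 and Gins2 by 0.46, and 7 when adjusted over the list alone (median 0.26, adjusted p 0.0118, adjusted p = 0.932 with an estimated correlation), with −0.071 to 0.46 within slides. Of 12 genes of microglia and macrophages 1 fell, Cx3cr1 at −0.45, also when adjusted over the list alone (median −0.25, adjusted p 0.00747, adjusted p = 0.932 with an estimated correlation), with −0.429 to 0.147 within slides. The call of the list DNA replication and G1/S, R-type versus S-type, was lost without MB2, MB6 or MB8 (adjusted p 0.0696, 0.0609 and 0.0541), and that of the list microglia and macrophage, R-type versus S-type, without MB6 or MB8 (adjusted p 0.0517 and 0.0541).

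Single genes changed in lists that did not pass. In the TGF-beta list Smad3 (0.64), Tgfb3 (0.93) and Tgfbr1 (0.59) rose and Tgfb2 fell, and in the Notch list Dll3 (1.78), Hey1 (0.52) and Rbpj (0.35) rose (adjusted p 0.201 for both lists, with 4 and 1 and with 5 and 0 genes higher and lower when adjusted over the list alone). In the SHH list Hhip (0.84), Sfrp1 (0.46) and Igf2 rose while Ptch1 and Bmi1 (−0.29) fell (adjusted p 0.745; 4 higher and 2 lower when adjusted over the list alone). Among genes of granule neuron precursors Pax6 (1.10) rose and Sox4 (−1.10), Barhl1 (−0.51) and Zic2 (−0.28) fell (adjusted p 0.745). Zic2 differed by −0.59 to 0.18 within slides, and by −0.03 to 0.16 within slides at 0.2 Gy, where R-type tumours were thus not clearly lower. Of 8 genes of GABAergic interneurons 1 rose and 2 fell, Nxph1 (−0.86) and Lhx1 (−0.33) (adjusted p 0.835). In the p53 list Pmaip1 (0.58) rose and Rrm2b (−0.39) fell (adjusted p 0.987, the median of 0.0354 and the mean of 0.0219 lying above 0 and the test pointing down). The DNA repair genes that rose included Atm (0.22) and Xrcc5 (0.29), and Fancc (−0.88) fell (adjusted p 0.387), and among imprinted genes Plagl1 and Igf2 rose (adjusted p 0.387). Single arrays left out ended the calls of Aldoa, Ldha, Rrm2, Hhip, Tgfbr1, Zic2, Lhx1, Pmaip1, Atm and Xrcc5, the highest adjusted p being that of Ldha, R-type versus S-type, at 0.0869 without MB11. Markers of normal cerebellum showed no list call: mature granule neurons had a median of −0.76 (adjusted p 0.192; 1 higher and 4 lower when adjusted over the list alone), Purkinje cells −0.19 (adjusted p 0.367), oligodendrocytes −0.48 (adjusted p 0.308), astrocytes 0.37 (adjusted p 0.716) and choroid plexus −1.08 (adjusted p 0.201). The endothelial list had an adjusted p of 0.0832, the meningeal list 0.716, the mitosis and oligodendrocyte precursor lists 0.745, the lymphocyte, blood and interferon lists 0.835, the immediate early list 0.966 and the WNT list 0.987. The WNT median of 0.08 and mean of 0.14 stood against a test pointing down.

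The share of changed genes that were higher depended on the scaling. It was 52.4% with the scaling used, 67.6% after a normexp background correction (3363 higher, 1612 lower) and 9% without scaling (577 higher, 5806 lower), the median over all genes being 0.022 with scaling and −0.199 without. With slide as a term the number of genes changed, R-type versus S-type, was 3653, and 3400 of the 4573 kept their call and direction. With age as a covariate, in a fit of the tumours only, limma called 0 genes (1607 at an unadjusted p under 0.05). Age separated the types, and the median SE of the 4573 genes rose from 0.101 to 0.368. How much of this rise came from leaving out the normal cerebella was not tested. The median size of the 4573 genes, regardless of sign, went from 0.464 to 0.402. Of these genes 85.6% kept their sign.

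Chromosome 13 carried more of the genes lower in R-type tumours than its size would give: 155 of the 1076 with a symbol, or 14.4%, against 3.6% of tested genes and 36 of the 1668 higher ones (2.16%). The 40 tested genes nearest to Ptch1, 20 on each side, had a median change of −0.53, with 20 lower, 3 higher and 17 not past the test. The size depended on the setting: for chromosome 13 near Ptch1, R-type versus S-type, the median was −0.335 after normexp, −0.235 with age as a covariate (adjusted p 0.000995) and −0.04 with no filter on dim probes (adjusted p 0.000312), where dim genes are among the nearest. Among them Habp4 (−1.22), Dapk1 (−1.14), Tut7 (−1.08), Gkap1 (−0.93), the Fanconi anaemia gene Fancc (−0.88) and Ercc6l2 (−0.69) fell, and Ntrk2 (0.77), Ctla2a (0.49) and Zfp369 (0.23) rose, all 9 being chosen after their values had been seen. Per tumour, the set stood at −0.49 ± 0.18 (SD, n = 6) in R-type and 0.00 ± 0.04 (SD, n = 6) in S-type tumours relative to the S-type mean (two-sided exact permutation test, p = 0.00216, the smallest that 924 splits can give). By camera the set was lower with an adjusted p of 3.31e-11, and 0.00103 with an estimated correlation. It was lower in all 6 R-type tumours, from −0.17 (MB9) to −0.65 (MB10), and within slides by −0.618 to −0.192. The 282 genes between Ptch1 and the centromere had a median of −0.40 (107 lower, 17 higher; adjusted p 2.4e-18, and 0.0164 with an estimated correlation). All 483 genes of the chromosome had −0.29 (154 lower, 36 higher; adjusted p 8.49e-12, and 0.0164 with an estimated correlation). The 201 genes beyond Ptch1 had −0.08 (47 lower, 19 higher; adjusted p 0.00339, adjusted p = 0.175 with an estimated correlation). Between tumours and normal cerebellum the 4 sets gave an adjusted p of 0.787.

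Along chromosome 13, the strongest stretch of neighbouring genes with lower signal held Ptch1 in each R-type tumour. The search returned 1 lower stretch for every tumour, so a further or a higher stretch could not show. This search was chosen after the values had been seen, and used 410 genes in chromosomal order. The stretch ran from Gdi2 to Mfsd14b in MB7 (238 genes, median −0.74), from Pak1ip1 to Med10 in MB8 (139 genes, −0.79), from Pitrm1 to Mfsd14b in MB9 (231 genes, −0.70), from Sirt5 to Ccdc127 in MB10 (148 genes, −0.66), from Carmil1 to Edil3 in MB11 (232 genes, −0.77) and from Prpf4b to 2210408I21Rik in MB12 (186 genes, −0.78). Each was stronger than in all 1000 shuffled gene orders (permutation p 0.001, the smallest that the shuffles can give). The signal inside was 0.577 to 0.631 of that in S-type tumours. All 6 stretches shared the 109 genes from Sirt5 to Mfsd14b, of which 87 were lower in R-type tumours, with a median of −0.78. No S-type tumour, measured against the mean of the other S-type tumours, had a stretch with Ptch1 beyond the shuffled orders. MB6 had one of 5 genes, from Zfp708 to Zfp595 (permutation p 0.015).

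**Figure D3:**
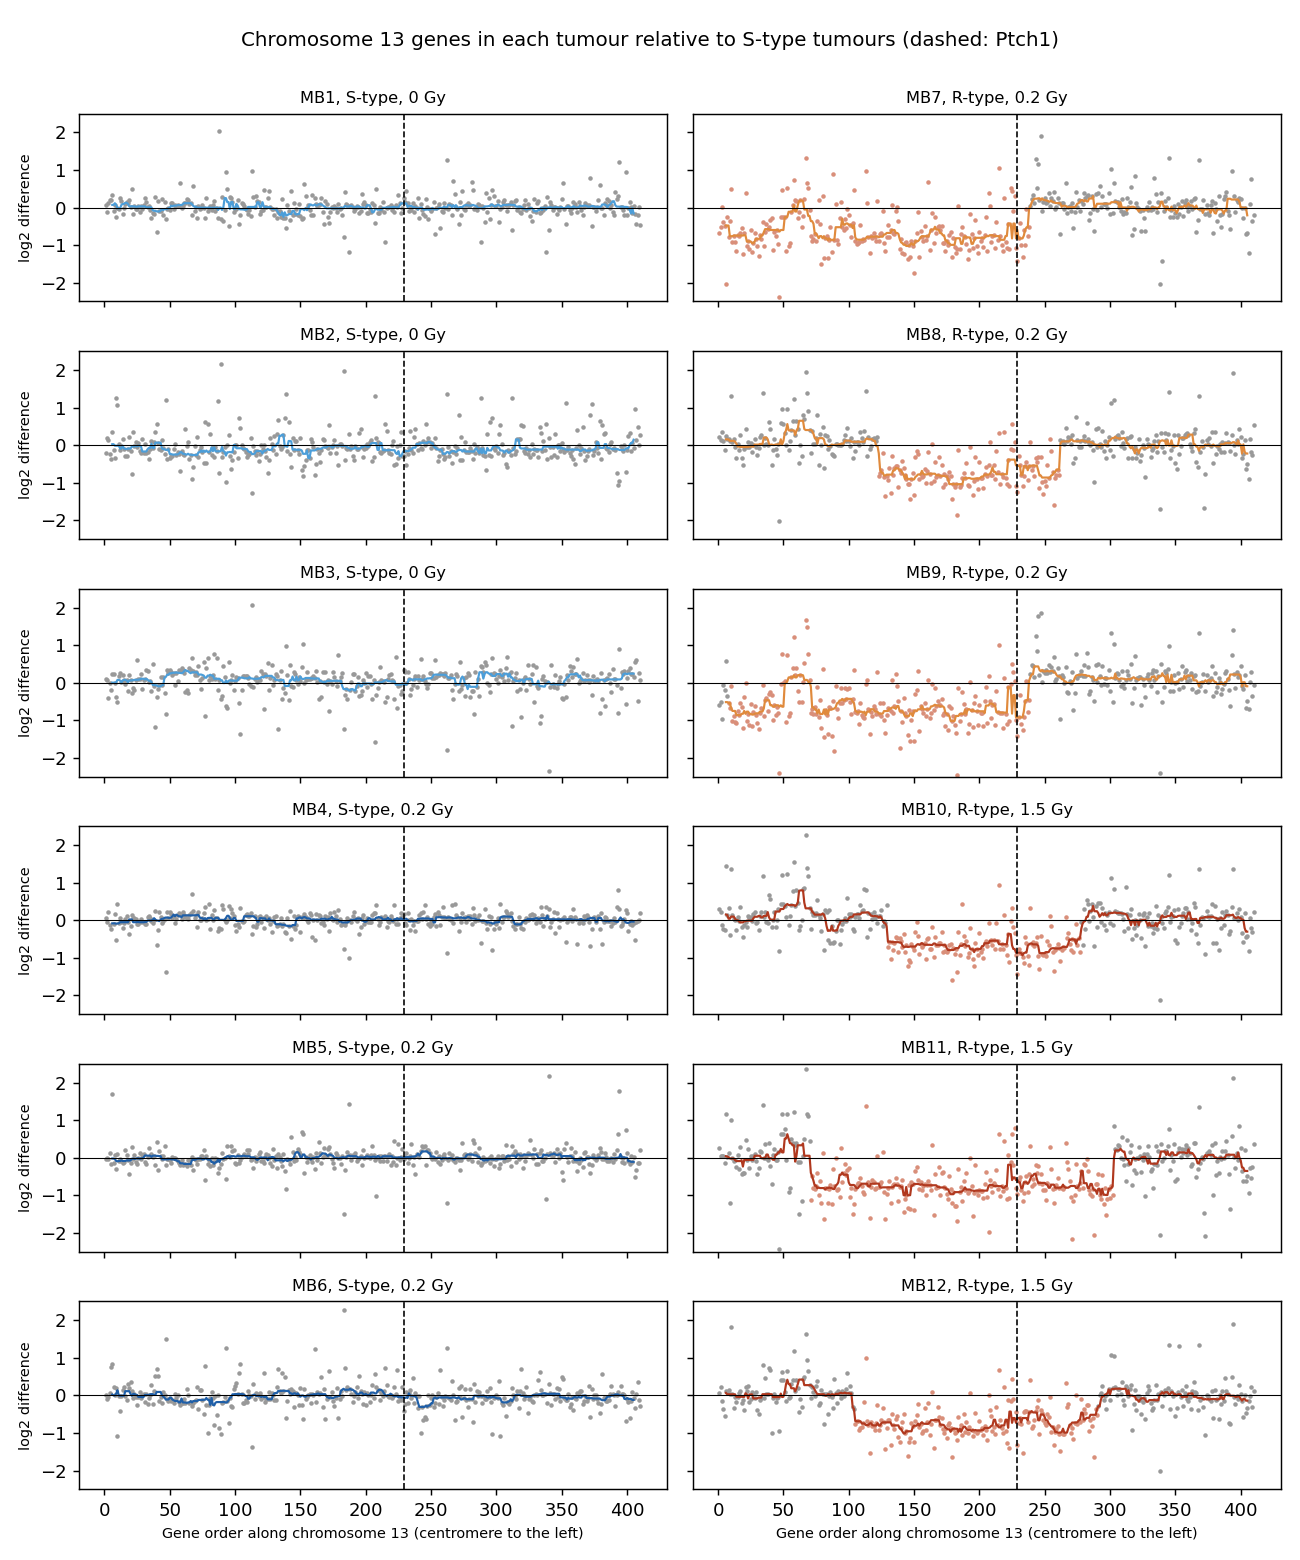
Log2 difference of 410 genes in order along chromosome 13 from the mean of the S-type tumours, with 1 panel per tumour, a running line and a dashed line at Ptch1. For an S-type tumour the mean is that of the other S-type tumours. Coloured points mark the stretch found in an R-type tumour. The line drops below 0 over 139 to 238 genes around Ptch1 in the 6 R-type tumours.

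At 0.2 Gy both types were available, and the comparison of MB7 to MB9 with MB4 to MB6 held the dose constant. It did not hold age or sex constant, MB6 being the only male. Ptch1 was lower in R-type tumours by 1.29 log2 units (log2 change −1.29, SE 0.169, adjusted p 0.00179), at −3.10 ± 0.10 (SD, n = 3) against −1.82 ± 0.24 (SD, n = 3), with −1.56 to −1.39 within the 2 slides that held both groups. The growth factor gene Fgf5 was higher by 3.62 (SE 0.518, adjusted p 0.0031), at 2.57 ± 0.69 (SD, n = 3) against −1.05 ± 0.28 (SD, n = 3). The neuronal adhesion gene Tenm3 (4.70, SE 1.17, adjusted p 0.0426) and Islr2 (3.25, adjusted p 0.0116) were higher too, and Igf2bp3 (at least 5.39-fold, adjusted p 0.0257) and Fgl1 (at least 2.21-fold, adjusted p 0.01) rose from below detection in the S-type group. Igf2 was higher by 2.87 (SE 0.62, adjusted p 0.0257). Lower were Mab21l2 (adjusted p 0.0322) and the diacylglycerol kinase gene Dgkb (adjusted p 0.000488), each well above background in 1 of 3 R-type tumours and given without a size. Lower too were Bend7 (at least 2.64-fold lower, adjusted p 0.00417), the nicotinic receptor gene Chrna10 (−2.86, adjusted p 0.0422), Lrba (−2.85, adjusted p 0.0149) and Ago4 (−2.73, SE 0.236, adjusted p 0.000129). Ago4 was well above background in 2 of 3 R-type tumours, and Tenm3 in 2 of 3 S-type tumours. Another probe of Ago4, the one used when only probes well above background on all 15 arrays were kept, gave 0.01 (adjusted p 0.973). Leaving out single arrays ended the calls of Chrna10, R-type versus S-type at 0.2 Gy (adjusted p 0.0504 to 0.162), Tenm3, R-type versus S-type at 0.2 Gy (0.0573 to 0.154), Mab21l2, R-type versus S-type at 0.2 Gy (0.0815 to 0.129), Igf2bp3, R-type versus S-type at 0.2 Gy (0.0582 to 0.106), Igf2, R-type versus S-type at 0.2 Gy (0.0649 to 0.097) and Lrba, R-type versus S-type at 0.2 Gy (0.0531 to 0.0681), in each case without MB4 and without MB9, and for all but Lrba without further arrays as well.

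In this comparison 1033 genes changed, 430 higher and 603 lower, and 95 of the 332 lower genes with a symbol (28.6%) lay on chromosome 13. The share higher was 41.6%, 60.4% after normexp (807 higher, 529 lower) and 5.9% without scaling (159 higher, 2515 lower). Of the 40 genes nearest to Ptch1, 17 fell and 0 rose, the other 23 not passing in limma (median −0.36; adjusted p 1.43e-09, and 0.00205 with an estimated correlation), with −0.44 to −0.211 within slides. With no filter on dim probes the median of chromosome 13 near Ptch1, R-type versus S-type at 0.2 Gy, was 0.06 while the test still pointed down (adjusted p 0.00443). The exact permutation p was 0.1, the smallest that 20 splits allow. The genes on the centromere side had a median of −0.50 (adjusted p 8.83e-24, and 0.0116 with an estimated correlation) and those beyond Ptch1 0.03 (adjusted p 0.84). Of the lists, 3 passed, none with an estimated correlation. No ribosomal protein gene passed over all genes, but 12 of 16 were higher when adjusted over the list alone (median 0.27, adjusted p 3.21e-06, adjusted p = 0.967 with an estimated correlation). Of 13 hypoxia and glycolysis genes Car9 (0.98) and Slc2a1 (0.55) rose, and 3 did when adjusted over the list alone (median 0.55, adjusted p 0.00241, adjusted p = 0.967 with an estimated correlation), with 0.0447 to 0.277 within slides. Of 14 interferon and MHC class I genes Usp18 (2.27) rose, and 6 did when adjusted over the list alone (median 0.41, adjusted p 0.00434, adjusted p = 0.967 with an estimated correlation), with 0.475 to 0.906 within slides. Without MB4, adjusted p-values were 0.0999 for Usp18, R-type versus S-type at 0.2 Gy, 0.0521 for Car9, R-type versus S-type at 0.2 Gy, and 0.0827 for Slc2a1, R-type versus S-type at 0.2 Gy. The median of the list hypoxia and glycolysis, R-type versus S-type at 0.2 Gy, was 0.35 without MB6 (adjusted p 0.0492), and the list lost its call without MB8 (adjusted p 0.0576). The ribosomal list lost its call with quantile normalization (list ribosomal protein, R-type versus S-type at 0.2 Gy, adjusted p 0.054). The other 23 lists had adjusted p-values of 0.101 or more; the astrocyte list stood at a median of 0.61 (adjusted p 0.286). The number of genes changed, R-type versus S-type at 0.2 Gy, rested on single arrays, being 295 without MB9, 388 without MB5, 403 without MB7, 430 without MB4 and 465 without MB6, and it was 444 with slide as a term and 117 with age as a covariate. With age, in a fit of the tumours only, the median size of the 1033 genes, regardless of sign, went from 0.767 to 0.799. Their median SE went from 0.146 to 0.203. All of them (100%) kept their sign, so the calls were lost without a smaller change.

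Within S-type tumours, MB4 to MB6 at 0.2 Gy were compared with MB1 to MB3 at 0 Gy. Only Zic2, a zinc finger transcription factor of granule neuron precursors, changed in limma, falling by 0.99 (SE 0.115, adjusted p 0.0454) to −1.23 ± 0.05 (SD, n = 3) from −0.24 ± 0.19 (SD, n = 3), with −1.12 to −1.05 within slides. At an unadjusted p under 0.05 stood 1247 genes, where chance gives 1084. Zic2, 0.2 Gy versus 0 Gy within S-type, lost its call without MB2, MB4, MB5 or MB6 (adjusted p 0.0696 to 0.25). For genes changed, 0.2 Gy versus 0 Gy within S-type, leaving out MB4 or MB6, or taking slide into the fit, gave 0, and leaving out MB1 gave 20. Ptch1 stood at −0.15 (adjusted p 0.992).

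As lists, genes of the Notch pathway were higher at 0.2 Gy (median 0.46, adjusted p 4.99e-05, adjusted p = 0.295 with an estimated correlation). Of its 11 genes 2 were higher when adjusted over the list alone, with Hes5 at 1.39, Jag1 at 0.81, Hey1 at 0.49 and Notch2 at 0.46. Higher too were those of oligodendrocyte precursors (median 0.65, adjusted p 0.00672, adjusted p = 0.339 with an estimated correlation; Olig1 at 1.26) and DNA repair (median 0.10, adjusted p 0.0119, adjusted p = 0.683 with an estimated correlation; Atm at 0.17). Choroid plexus genes were lower, with 4 of 7 lower when adjusted over the list alone and Clic6 at −2.69 and Folr1 at −2.26 (adjusted p 4.99e-05, adjusted p = 0.295 with an estimated correlation). The mean of that list was 1.02 ± 1.67 (SD, n = 3) at 0 Gy and −0.95 ± 0.31 (SD, n = 3) at 0.2 Gy relative to normal cerebellum. Lower too were the lists of immediate early genes (median −0.21, adjusted p 0.00672, adjusted p = 0.339 with an estimated correlation; Npas4 at −1.60), mature granule neurons (−0.59, adjusted p 0.00672, adjusted p = 0.683 with an estimated correlation; Slc17a7 at −2.48), Purkinje cells (−0.19, adjusted p 0.0194, adjusted p = 0.295 with an estimated correlation), interferon and MHC class I (−0.16, adjusted p 0.0326, adjusted p = 0.683 with an estimated correlation) and oligodendrocytes (−0.32, adjusted p 0.0411, adjusted p = 0.683 with an estimated correlation). No member of these 9 lists passed over all genes, and Slc17a7, Folr1 and Npas4 were well above background in 2 of 3 tumours at 0.2 Gy. The mature granule neuron list ranged from −2.20 to 0.054 within slides, and without MB2 its median shrank to −0.035 and the test pointed up. The Notch and choroid plexus lists passed with each array left out in turn but their sizes rested on few arrays. The median of the list Notch pathway, 0.2 Gy versus 0 Gy within S-type, was 0.235 without MB3 (adjusted p 0.021), and its mean difference was 0.573 on slide 1 and 0.019 on slide 4. The choroid plexus list stood at 2.48 in MB2 and 1.39 in MB3 relative to normal cerebellum but at −0.80 in MB1, among the values of −1.24 to −0.63 at 0.2 Gy. Its mean difference was −3.10 on slide 1 and −0.43 on slide 4. Without MB2, MB3 and MB6 only MB1 was left at 0 Gy. That setting therefore does not decide on the Notch or the choroid plexus list. The others lost their call without some arrays: DNA repair without MB2, MB4 or MB5 (list DNA damage repair, 0.2 Gy versus 0 Gy within S-type, adjusted p 0.0633 to 0.57), mature granule neurons without MB2 (list mature granule neuron, 0.2 Gy versus 0 Gy within S-type, adjusted p 0.905), immediate early genes without MB2 (list immediate early, 0.2 Gy versus 0 Gy within S-type, adjusted p 0.471) and oligodendrocyte precursors without MB1 (list oligodendrocyte precursor, 0.2 Gy versus 0 Gy within S-type, adjusted p 0.0851). So did the lists of Purkinje cells without MB2, MB3, MB5 or MB6 (list Purkinje cell, 0.2 Gy versus 0 Gy within S-type, adjusted p 0.0504 to 0.131), interferon and MHC class I without MB1, MB2, MB4 or MB5 (list interferon and MHC class I, 0.2 Gy versus 0 Gy within S-type, adjusted p 0.0961 to 0.48) and oligodendrocytes without MB1, MB2, MB4 or MB6 (list oligodendrocyte, 0.2 Gy versus 0 Gy within S-type, adjusted p 0.171 to 0.317). The other 17 lists had adjusted p-values of 0.0627 or more.

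Within R-type tumours, MB10 to MB12 at 1.5 Gy were compared with MB7 to MB9 at 0.2 Gy. Ndufs6, a subunit of respiratory complex I, fell by 1.00 (SE 0.081, adjusted p 0.000963) to 3.06 ± 0.11 (SD, n = 3) from 4.06 ± 0.06 (SD, n = 3), with −1.10 to −0.89 within slides. Mrpl36 (−0.97, adjusted p 0.00288), Brd9 (−0.92, adjusted p 0.0011), Clptm1l (−0.84, adjusted p 0.00468), Zfp825 (−0.84, adjusted p 0.00161) and Pdcd6 (−0.82, adjusted p 0.0011) fell too. These 6 were among 15 changed genes, 14 lower and 1 higher, of which 9 had a symbol; Ccdc127 (−0.81), Sdha (−0.78) and Trip13 (−0.77), singled out after their values had been seen, were the others. All 9 lie on chromosome 13. In gene order they follow Med10, the last gene of the lower stretch of MB8, and fall inside the stretches of MB10, MB11 and MB12, except that the stretch of MB10 ended before Zfp825. Ptch1 stood at 0.13 (adjusted p 0.936), and Igf2 at −2.78 (adjusted p 0.391).

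Of the lists, 4 were lower at 1.5 Gy, none with an estimated correlation, and no member passed over all genes. Of the 14 interferon and MHC class I genes 10 were lower when adjusted over the list alone, with Isg15 at −1.22, Ifit3 at −1.07 and H2-K1 at −0.44 (median −0.47, adjusted p 2.88e-11, adjusted p = 0.215 with an estimated correlation), and −0.829 to −0.519 within slides. The list of microglia and macrophages was lower (C1qa at −0.48, Cx3cr1 at −0.34; median −0.39, adjusted p 2.86e-08, adjusted p = 0.442 with an estimated correlation). Its mean relative to normal cerebellum was 1.80 ± 0.14 (SD, n = 3) against 2.21 ± 0.24 (SD, n = 3). The list of astrocytes and Bergmann glia was lower as well (Aqp4 at −1.93, Hopx at −1.62, Apoe at −0.56; median −0.72, adjusted p 3.06e-05, adjusted p = 0.442 with an estimated correlation). Its means were −3.41 ± 0.53 (SD, n = 3) and −2.57 ± 0.77 (SD, n = 3) relative to normal cerebellum. MB7 stood apart at −1.80, against −3.35 in MB8 and −2.56 in MB9, and without it the median of the list astrocyte and Bergmann glia, 1.5 Gy versus 0.2 Gy within R-type, was −0.45 (adjusted p 0.0369). So was the p53 list (Cdkn1a at −0.75, Plk2 at −0.71, Phlda3 at −0.71; median −0.25, adjusted p 0.000603, adjusted p = 0.442 with an estimated correlation), with 1 of 19 lower when adjusted over the list alone. The other 22 lists had adjusted p-values of 0.0508 or more. The number of genes changed, 1.5 Gy versus 0.2 Gy within R-type, was 158 without MB8, 27 without MB11, 25 without MB10 and 9 without MB9.

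By chromosome, the median difference from normal cerebellum, less that over all genes, was highest on chromosome 6, at 0.30 ± 0.17 (SD, n = 12), from −0.029 in MB6 to 0.70 in MB3; the chromosome did not pass camera between tumours and normal cerebella (adjusted p 0.981, 0.988 with an estimated correlation). On chromosome 13 it was −0.21 ± 0.12 (SD, n = 6) in R-type and 0.09 ± 0.06 (SD, n = 6) in S-type tumours. Between the types only chromosome 13 passed camera (adjusted p 6.41e-11, adjusted p = 0.16 with an estimated correlation), the next having an adjusted p of 0.115. Relative to the other tumours, chromosome 6 stood at 0.394 in MB3 and at −0.38 in MB6.

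**Figure D4:**
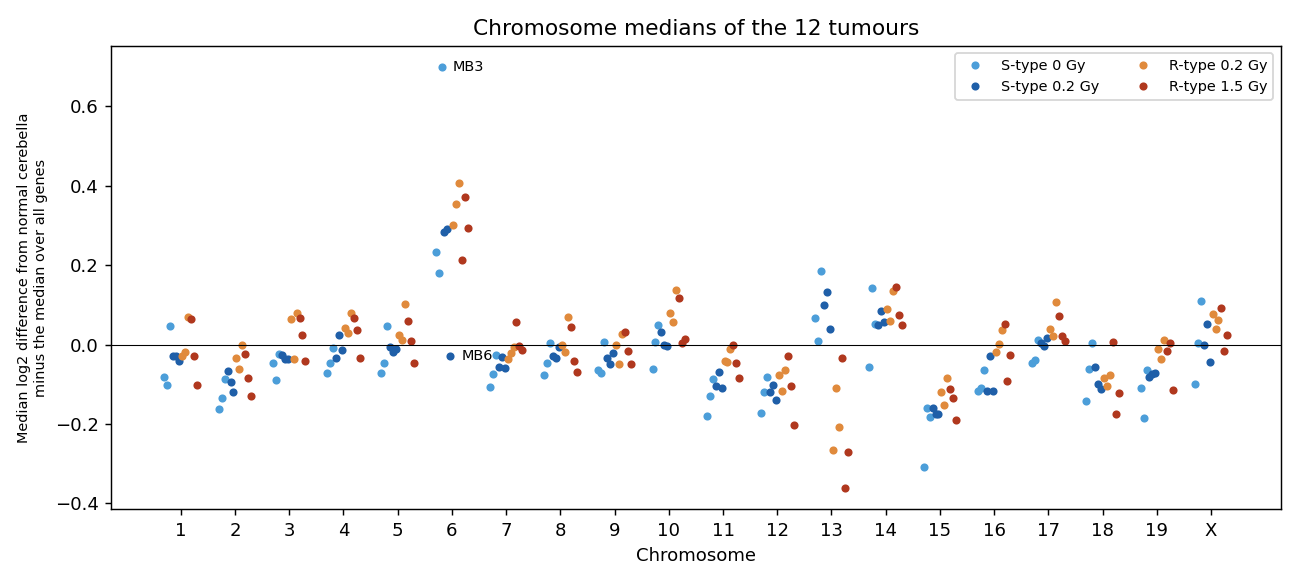
Median log2 difference from normal cerebellum of the genes of each chromosome, less the median over all genes, with 1 point per tumour. MB3 and MB6 lie apart at chromosome 6, and the R-type tumours lie low at chromosome 13.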

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

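The tests of chromosome 13 and of chromosome 6 below, and the reading of dose, were chosen only after the results were seen, and those of age, array signal and normal tissue before. The lower signal of genes around Ptch1 in all 6 R-type tumours may reflect the loss of 1 copy of a stretch of chromosome 13 that holds Ptch1. Inside the stretch the medians of the 6 R-type tumours were −0.793 to −0.664, and no S-type tumour had such a stretch with Ptch1. Each S-type tumour was measured against the other S-type tumours, so a change shared by all of them could not show. Relative to normal cerebella, the 40 genes nearest to Ptch1 stood at 0.045 to 0.20 in S-type and at −0.71 to −0.18 in R-type tumours. A lower signal or the scaling of the R-type arrays is argued against only as an effect on all chromosomes alike. Genes of other chromosomes matched on signal had a median of 0.0503, where the 109 shared genes had −0.778. The scaling holds the median of many genes near 0, but without it the median over all genes was only −0.199. The 109 genes were picked as low in these same arrays. The 40 genes nearest to Ptch1, taken by position, had a median of −0.53. Slide is argued against as the whole cause: all 4 slides held both types and differed downward (−0.618 to −0.1918, the last missing the bound of −0.2), and with slide as a term, which brought the genes changed, R-type versus S-type, from 4573 to 3653, the nearest genes stood at −0.498 (camera adjusted p 6.45e-10). Age and dose, which differ between the types, were not excluded as conditions under which such a loss arises, and with age as a covariate chromosome 13 near Ptch1, R-type versus S-type, stood at −0.235 (adjusted p 0.000995).

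Chromosome 6 stood higher in MB3 (0.394) and lower in MB6 (−0.38) than in the other tumours, which may reflect different numbers of copies of the whole chromosome. Relative to normal cerebellum it stood at 0.70 in MB3, at −0.029 in MB6 and at 0.18 to 0.41 in the other tumours, so that MB6 lay near the normal level. Against the other tumours, each of 4 parts of the chromosome shifted the same way, by 0.301 to 0.423 in MB3 and by −0.388 to −0.349 in MB6. Fewer detected probes on these arrays are argued against, since the shifts had opposite signs and no other chromosome but 13 shifted by more than 0.0759. The comparison of doses in S-type tumours, which holds both, had a median of −0.18 on chromosome 6 (camera adjusted p 7.52e-10, 0.861 with an estimated correlation), and that of the types at 0.2 Gy, which holds MB6, also passed there (adjusted p 0.000438, 0.774 with an estimated correlation). So did that of doses in R-type tumours, which holds neither, with a median of −0.061 (camera adjusted p 0.0141, 0.992 with an estimated correlation). What else may lie behind the shifts was not tested.

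The types differed in many genes off chromosome 13, and 3 explanations were set against this. The change predicted from age within the types had a coefficient of 0.131 on the change between the types (0.0728 to 0.16 with each tumour left out, permutation p = 0.067, one-sided), under the bound of 0.5. Within each type, however, all mice at the higher dose were younger than those at the lower dose. The slope therefore cannot part age from dose and does not decide on age. An age effect that is not linear stays open too. The signal level of the arrays had a coefficient of 0.000894 (−0.0411 to 0.17; permutation p = 0.54, one-sided). More normal cerebellar tissue in S-type tumours is argued against as the main source only. Of the 2020 called genes lower in R-type tumours, 46.8% were higher in normal cerebellum, under the bound of 60%. That share lay above the 24.7% of the 2362 higher ones and the 35.4% of all genes, the direction that more normal tissue would give. A partial share of normal tissue therefore stays open. Dose is argued against as the whole source, since genes off chromosome 13 also differed between the types at 0.2 Gy. Of the 1033 genes called there, 286 higher and 332 lower ones had a symbol, and 9 and 95 of these lay on chromosome 13. Doses within a type differed in 1 and 15 genes, but these counts do not decide. Simulated changes of 0.5 log2 units, put into few genes, were recovered there in only 26.9% (S-type) and 28.4% (R-type) of these genes. A change of many genes was not simulated. Dose stays open for genes called only over both doses, as does what distinguishes the types in the labels, which was not tested further.

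Values far from the rest of a type (6 tumours) were found in 18 of 190 groups of values, where chance marks about 1 in 20, or 9.5. MB2 stood apart from the other S-type tumours in the lists of mature granule neurons (−3 against −5.2 to −4.47) and immediate early genes (0.0596 against −0.917 to −0.586), and on chromosome 3 (−0.09 against −0.0465 to −0.0234) and chromosome 19 (−0.184 against −0.109 to −0.0648). MB7 stood apart from the other R-type tumours in the lists of blood (0.36 against −0.584 to −0.264), choroid plexus (−0.444 against −1.18 to −0.97) and DNA repair (2.78 against 2.87 to 2.91). MB1 was apart in the TGF-beta list (0.749 against 0.55 to 0.624) and on chromosome 15 (−0.307 against −0.182 to −0.16). MB11 was apart in the Purkinje cell list (−6.69 against −6.07 to −5.8), in Calb1 (−7.22) and in Tenm3 (−5.09 against −0.995 to 1.24), and MB10 on chromosome 7 (0.0565 against −0.036 to −0.00432). MB6 was apart in Calb1 (−6.36) and Ago4 (−1.42 against −2.53 to −2.14), MB3 in Etnppl (−4.76) and Igf2bp3 (−3.7), and MB9 in Tgfb2 (−0.805 against −0.243 to 0.0193). The distances in Calb1, Etnppl and Igf2bp3 have no meaningful size, since MB6 and MB11 were not well above background in Calb1, and MB3 was the only S-type tumour above it in the other 2 genes. No explanation was tested for these values.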

How the results depend on the processing

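The settings that leave out MB2, MB3 and MB6 together or chromosome 13, and the other scalings for chromosome 6, were chosen only after the results were seen. The genes changed, tumour versus normal (17094), the 12 of 26 lists and the counts of each tumour group against normal cerebellum stayed within 1.5 times under every setting except a 2-fold minimum (9911) and an estimated correlation between list genes (1 list, and 0 lists in each of the other 4 comparisons). The genes changed, R-type versus S-type (4573), stayed within that range under all scalings, filters and fits but became 0 with age as a covariate, 658 at 2-fold, 1861 at an adjusted p of 0.01 and 3036 without MB9. With age, limma called 1607 genes at an unadjusted p under 0.05. The fit with age held the tumours only, so the normal cerebella were missing from it too. Age separates the types, the median SE of the 4573 genes went from 0.101 to 0.368, and 85.6% of them kept their sign. The 4 lists became 2 with sex, with age, without MB6 and without MB8. Ptch1 stood at −1.53 with age (SE 0.461, adjusted p 0.507) against −1.30 (SE 0.12). Signs that turned with age, none past the threshold, were those of the replication list (−0.138), Aldoa (−0.0171), Ldha (−0.24), Mab21l2, R-type versus S-type (0.0941), Mal (−0.54), Mcm5 (−0.18), Rfc4, R-type versus S-type (−0.0887), Rps2, R-type versus S-type (−0.0420), Sfrp1, R-type versus S-type (−0.0903), Trim55 (−0.33) and Xrcc5 (−0.24). The genes changed, R-type versus S-type at 0.2 Gy (1033), became 539 without a filter on dim probes, 456 with only the compared groups in the fit, 465 with sex, 117 with age, 444 with slide. With age, the median size of the 1033 genes went from 0.767 to 0.799 and their median SE from 0.146 to 0.203, and 100% kept their sign. The count was 332 at 2-fold, 218 at an adjusted p of 0.01 and 4630 with array weights. The weights put 62.6% of the S-type weight on MB5 and 53.3% of the R-type weight on MB9, both on slide 4. Ago4, R-type versus S-type at 0.2 Gy, turned to 0.0148 when probes had to be well above background on all 15 arrays, since another of its probes was then used. The genes changed, 0.2 Gy versus 0 Gy within S-type (1), became 2 with quantile normalization, 3 with the array median, the series table, a filter by group or without chromosome 13, and 0 without a filter, with only the compared groups, with sex, age, weights or slide, at 2-fold and at an adjusted p of 0.01 (1247 genes at an unadjusted p under 0.05 in limma before). Its 9 lists became 5 with weights. Without MB2, MB3 and MB6 only MB1 was left at 0 Gy, so no counts are given for that setting. With age the lists of choroid plexus (0.148), DNA repair (−0.204), interferon (list interferon and MHC class I, 0.2 Gy versus 0 Gy within S-type, where the test turned upward and the median was −0.00423) and mature granule neurons (0.212) turned, and the last also without MB2, MB3 and MB6 (0.0695). Without MB2 the test of the last turned upward while its median stayed below 0 (−0.035, the range over arrays left out being −1.03 to −0.035). The genes changed, 1.5 Gy versus 0.2 Gy within R-type (15), became 0 with only the compared groups or with age (1531 at an unadjusted p under 0.05 in limma before), 2 at 2-fold, 8 at an adjusted p of 0.01 and 5 without chromosome 13, and the 4 lists became 8 with slide. Fits of fewer groups have fewer residual degrees of freedom, and stricter thresholds call fewer genes by construction. For the other changes the cause was not tested. Leaving out each array in turn gave 16169 to 17222 genes for tumours against normal cerebella, 3036 to 5289 between the types, 295 to 933 at 0.2 Gy (295 without MB9, 388 without MB5, 403 without MB7, 430 without MB4, 465 without MB6), 0 to 20 between doses in S-type (20 without MB1, 2 without MB5, 0 without MB4 or MB6) and 9 to 158 in R-type tumours (158 without MB8, 27 without MB11, 25 without MB10, 9 without MB9). Lists numbered 12 to 13, 2 to 6, 3 to 4, 4 to 12 (4 without MB2) and 4 to 7 (7 without MB12) in the same order. The genes near Ptch1 stayed lower in R-type tumours, at −0.59 to −0.379, and at −0.425 to −0.309 at 0.2 Gy, as arrays were left out. With no filter on dim probes the test still passed downward while the medians were −0.039 and 0.0641. Counting every setting, those above included, 11960 values of named genes kept direction and side of the threshold, 368 lost and 139 gained a call, 150 moved and 11 reversed. Of the values of single lists 2817 kept both, 89 lost and 69 gained a call, 211 moved and 7 reversed. No paired analysis was possible because the numbers 1 to 3 that normal cerebella and S-type tumours at 0 Gy share name different mice, and samples of the same number correlated at 0.0461, −0.0239 and 0.00129 after group means were removed. Signal over background limits genes near the floor: changes are bounds where no array of a group was above it, and sizes depend on the floor where some were not.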

Other observations

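The counts of other splits were planned before the results were seen, while the group means and Xist values given first were picked only after the result was seen, without a test. The mean of the interferon and MHC class I list, relative to normal cerebellum, was 0.60 ± 0.33 (SD, n = 3) in S-type tumours at 0 Gy, 0.19 ± 0.06 (SD, n = 3) in S-type at 0.2 Gy, 0.93 ± 0.27 (SD, n = 3) in R-type at 0.2 Gy and 0.22 ± 0.36 (SD, n = 3) in R-type at 1.5 Gy. Igf2 was likewise highest in R-type tumours at 0.2 Gy, at 3.92 ± 0.70 (SD, n = 3), against 1.14 ± 0.64 (SD, n = 3) in R-type at 1.5 Gy and 1.06 ± 0.18 (SD, n = 3) in S-type at 0.2 Gy. Xist was low in MB3 and MB9 among the tumours labelled female, while the genes of the X chromosome had medians of 0.0759 and 0.0515 in them relative to the other tumours.

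Other splits of the same samples were counted. For tumours against normal cerebella, the real split, with 1 mean per side, called 16594 genes and the highest of 99 others 2, and for the types 4714 and 43. In both cases 1 of 100 splits, the real one, reached the count, the smallest share that 100 splits can give. Chance is thus unlikely to account for these counts, though not all of the 455 and 462 possible splits were counted. The other comparisons have 10 splits, too few for a share under 0.05. At 0.2 Gy the real split of the types called 1033 genes and the highest other 0 (1 of 10 splits as high). Each tumour group against normal cerebellum called 16088, 16008, 16054 and 16153 genes, and the highest others 2, 1, 3 and 0. Between doses in S-type tumours the real split called 1 gene, and 8 of 10 splits called as many. The highest, that of MB1, MB3 and MB4 from MB2, MB5 and MB6, called 51, several times the real count, so the split by dose did not stand out. Whether the samples have another structure, and what sets them apart, was not tested. Between doses in R-type tumours the real split called 15 genes, and the split that put MB7, MB9 and MB11 together also called 15 (2 of 10 splits as high).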
